A study of Aplysia californica with 8 samples.

How the data were processed

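Gene expression was measured in pleural ganglia of the sea hare Aplysia californica on 8 two-colour Agilent arrays. The pleural ganglia are paired clusters of the central nervous system that hold the cell bodies of sensory neurons responding to noxious touch. Per the labels' protocols, training consisted of 4 rounds of shock to 1 side of the body at 30 min intervals, each of 10 pulses of 500 ms at 1 Hz and 90 mA, and ganglia were taken 1 h after training. Each RNA sample pooled the ganglia of 2 animals, of which 1 was trained on the left and 1 on the right, and 300 ng of total RNA was amplified and labelled. RNA of the trained side carried Cy5 (red) and RNA of the untrained side of the same 2 animals carried Cy3 (green) on every array, so the array itself is the pair and no dye swap was made. The labels call the 8 arrays biological replicates.

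The deposited scanner tables come from Agilent Feature Extraction 11.5.1.1, per the file headers, and give for each spot a foreground and a local background intensity in both channels, which are not normalized. They also hold processed intensities, which the scanner software had background-subtracted and dye-normalized, and a log10 ratio of red over green, per the file headers. That log10 column was compared with the processed signals (r = 0.989 across spots and arrays) and entered no test. The authors also deposited a value table of the same arrays, and its log2 values match red over green: across spots they correlated at 0.991 to 0.993 with loess-normalized log2 ratios of the median foreground, array by array. The medians of its columns lie between 0.00082 and 0.00569. The submitters' processing notes name limma, and its settings are not given in the sources used here. Per the file headers all 8 arrays lie on 1 slide and came from 1 scan. Replicates 1 to 4 lie in the first row of the slide and replicates 5 to 8 in the second, as the names of the deposited tables give them. The descriptions in the labels differ for replicates 7 and 8, where they repeat the position of replicate 6 with a suffix; the tables listed for each sample were used.

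Each array has 62976 spots, of which 61657 are not controls and carry 61615 probes for 26091 targets. The background was corrected with normexp (offset 50) on the mean foreground and median background intensities, over all spots. Each array was then normalized by loess with control spots at weight 0, in R 4.3.3 with limma 3.58.1. Spots marked as outliers by the scanner software were left out (0 to 3 per array), and no non-control spot was saturated. A probe was kept where it was well above background in at least 1 channel on at least 4 arrays, which left 43550 probes and 20104 targets. Spots of a probe were averaged, then the probes of a target. The log2 ratio of trained over untrained was tested against 0 over the 8 arrays with limma's lmFit and eBayes (two-sided), and the p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Values are given as mean ± SD over arrays. Between 40080 and 43163 non-control spots were well above background in the untrained channel, and between 39923 and 43364 in the trained channel. The number of arrays limits the precision. The spike-in controls returned a slope of 0.818 to 0.842 of observed on expected log ratio, per the file headers; that slope is the scanner software's and was not measured for the log2 ratios used here.

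Targets carry the identifiers of the array design. Of the 26091 targets, 639 have a similarity description in the files, often to a distant species, and 2 match the given RefSeq table of assembly AplCal3.0. Some other identifiers hold a name themselves, such as apnalcn, and the files pair most of the rest with none. C/EBP, a transcription factor chosen to be named always, was searched for by name and met no identifier or description. Of the tested targets, 19754 have no similarity description. A search by name cannot tell whether C/EBP is among them, so C/EBP is not shown to be unmeasured. The rule for the targets named was fixed before the data were examined. It takes, per direction, the 12 largest changes past the threshold with 1 sign on at least 7 arrays and an informative description, up to 2 identifiers without a description that changed more than the last of these, and the passing members of the lists. Descriptions that only say hypothetical, unnamed or uncharacterized, or that give only a locus code, did not count as informative; that wording was settled after the descriptions of the called targets had been seen, and it left 8 of 31. The contents of the 22 gene lists were fixed before the data were examined, while the search words that match them to identifiers and descriptions were written afterwards, with the descriptions at hand. Matching is by word, so the cytoskeleton list holds a midasin-like target and the kinase and growth factor lists share a kinase anchor protein. A list with at least 3 tested members was tested with limma's camera (preset inter-gene correlation 0.01) and fry.

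The fit was tested on simulated data made from the residuals of the real probes, with 200 targets changed by known sizes among 20104. For the comparison of trained with untrained it recovered 50.7% of 67 targets changed by 0.25 on the log2 scale, 98.5% of 67 changed by 0.5 and 97.0% of 66 changed by 1, with 6 false calls beside 164 true ones. Signs were redrawn for each target and array, which removes correlation between targets and any dye effect common to the arrays. The false calls therefore do not give the error rate of the real comparison. Alternatives covered the background correction, the foreground statistic, the normalization within and between arrays, the filter on dim probes, the level of the test, the pairing of the channels, the variance model, the slide row, the deposited value table, the threshold, and leaving out each array. Alternatives on the sequence of the probes, on centring over the tested probes and on the pairing of replicates 6 and 7 were chosen after seeing the data. For these, a GT repeat is a run of at least 8 bases of alternating G and T, and 2 probes of a target count as non-overlapping where they share no 12 bases.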

Results

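Long-term sensitization is a lasting increase of a defensive reflex after repeated noxious stimulation, and the series asked how transcript levels in the pleural ganglia change shortly after training. The data are 8 arrays in 1 group. Each array set the RNA of the trained side of 2 animals (Cy5) against the RNA of the untrained side of the same 2 animals (Cy3), 1 h after 4 rounds of shock. Animals came from at least 2 shipments. The untrained side is thus the control on each array, measured with the same probes. Of 61657 non-control spots, 39923 to 43364 were well above background in the trained channel and 40080 to 43163 in the untrained channel.

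The trained channel read higher for 978 targets and lower for 458 targets among the 20104 tested (limma, Benjamini-Hochberg adjusted p under 0.05, n = 8 arrays). Trained RNA was in Cy5 on every array, so these counts cannot tell training from a dye effect. Of the 978 targets, 143 were read by a probe with a GT repeat, taken up below. The counts depended on single arrays and on the variance model: 661 rose and 245 fell without replicate 1, 643 and 313 without replicate 3, 529 and 184 without replicate 4, and 638 and 236 without replicate 5. With trend and robust variances 764 rose and 44 fell (94.6% rising). The changes were mostly small, with a median of 1.17-fold for targets that rose and 1.16-fold for targets that fell. At least 1.5-fold was reached by 32 targets that rose and by 0 that fell, and at least 2-fold by 3 that rose. The largest rise past the threshold was that of U00994.1, whose trained side was 3.06-fold higher, a log2 ratio of 1.61 ± 0.65 (SD, n = 8, limma adjusted p = 4.5e-04). It was higher on 8 of 8 arrays, from 0.85 to 2.67. Both of its probe sequences, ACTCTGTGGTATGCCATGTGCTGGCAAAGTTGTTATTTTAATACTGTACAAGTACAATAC and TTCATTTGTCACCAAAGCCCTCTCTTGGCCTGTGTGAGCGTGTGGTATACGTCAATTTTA, rose, the latter by a log2 ratio of 1.66 ± 0.67 (SD, n = 8). EB251115.1, read by the single probe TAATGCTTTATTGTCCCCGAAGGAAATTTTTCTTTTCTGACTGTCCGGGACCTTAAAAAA, rose by a log2 ratio of 1.21 ± 0.40 (SD, n = 8, limma adjusted p = 2.0e-04) and was higher on 8 of 8 arrays. The largest falls past the threshold were EB253887.1 and EB349078.1, with log2 ratios of -0.51 ± 0.42 and -0.48 ± 0.27 (SD, n = 8, limma adjusted p = 0.024 and 0.0047). EB349078.1 was lower on 8 of 8 arrays, through 3 probes that overlap almost fully and so read 1 stretch of sequence. EB253887.1 was above 0 on 1 array and lost its call without replicate 1, 4 or 5 (limma adjusted p = 0.0617, 0.0505 and 0.0573). The files give these 4 identifiers no name.

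**Figure D1:**
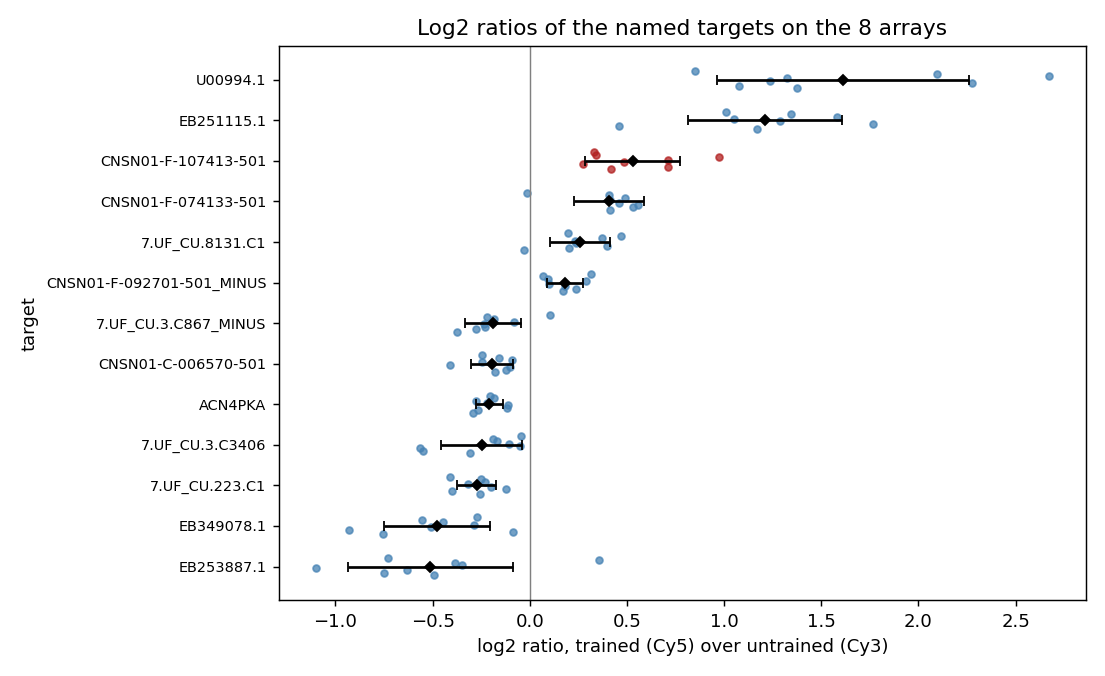
Log2 ratio of trained (Cy5) over untrained (Cy3) on the 8 arrays (points) for the 13 named targets, with the mean and SD (diamond and bar); red points mark the 1 target read by a probe with a GT repeat. U00994.1 lies between 0.85 and 2.67 on all 8 arrays, and ACN4PKA lies below 0 on all 8.

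Of the 350 tested targets with a similarity description, 18 rose and 13 fell, and 8 of these 31 had a description that names a protein. ACN4PKA (gi_5587_emb_X62382.1_ACN4PKA_A.californica_), matched to the kinase list by the letters PKA in its identifier, fell in the trained side with a log2 ratio of -0.21 ± 0.07 (SD, n = 8, limma adjusted p = 0.0073) and was lower on 8 of 8 arrays. Its 3 probes, which differ in sequence, had log2 ratios of -0.20, -0.22 and -0.21, each past the threshold. Protein kinase A is the kinase activated by cyclic AMP. The identifier does not say which subunit the target encodes, and the sensitization list was written for a regulatory subunit. The fall can therefore not be read as a fall of the kinase itself. A target similar to a sponge heat-shock protein Hsp70 (7.UF_CU.3.C867_MINUS) fell with a log2 ratio of -0.19 ± 0.14 (SD, n = 8, limma adjusted p = 0.0446), and its call was lost without any 1 of replicates 2 to 8 (limma adjusted p = 0.0712 to 0.0970). After the dinucleotide content of the probes was regressed out, its log2 ratio was -0.10 and did not pass. Hsp70 proteins are chaperones that help other proteins fold. Among other described targets, one similar to a putative helicase (CNSN01-F-074133-501) rose by a log2 ratio of 0.41 ± 0.18 (SD, n = 8, limma adjusted p = 0.0018). One similar to a histidine-rich protein (7.UF_CU.8131.C1) rose by 0.26 ± 0.15 and one similar to a glutamic acid-rich protein (CNSN01-F-092701-501_MINUS) by 0.18 ± 0.09 (SD, n = 8, limma adjusted p = 0.0133 and 0.0216), the latter losing its call without replicate 1 or 4 (adjusted p = 0.0595 and 0.0662). A target similar to a chloroplast cytochrome c synthesis protein (CNSN01-F-107413-501) read 0.53 ± 0.24 (SD, n = 8, limma adjusted p = 0.0017), through a single probe that holds a GT repeat. With the dinucleotide content of the probes regressed out, CNSN01-F-107413-501 and 7.UF_CU.8131.C1 read 0.16 each and did not pass (limma adjusted p = 0.140 and 0.105). Targets similar to a coronavirus membrane protein (7.UF_CU.223.C1), a bacterial lipooligosaccharide enzyme (7.UF_CU.3.C3406) and a papillomavirus protein (CNSN01-C-006570-501) fell, with log2 ratios of -0.27 ± 0.10, -0.25 ± 0.21 and -0.19 ± 0.11 (SD, n = 8, limma adjusted p = 0.0028, 0.0393 and 0.0202). With the dinucleotide content regressed out, 7.UF_CU.3.C3406 read -0.25 and did not pass (limma adjusted p = 0.0560). Its call was also lost without replicate 2, 3, 4, 6, 7 or 8 (adjusted p = 0.0631 to 0.0818) and that of CNSN01-C-006570-501 without replicate 1 or 4 (adjusted p = 0.0533 and 0.0599). Several of these calls were also lost under other settings (limma adjusted p throughout). With the scanner software's processed signals, 7.UF_CU.3.C867_MINUS (0.0506), 7.UF_CU.8131.C1 (0.0943), EB253887.1 (0.09998), 7.UF_CU.3.C3406 (0.149), CNSN01-F-092701-501_MINUS (0.150) and CNSN01-C-006570-501 (0.183) did not pass. With trend and robust variances, CNSN01-C-006570-501 (0.0645), EB349078.1 (0.0676), 7.UF_CU.3.C3406 (0.0851), 7.UF_CU.3.C867_MINUS (0.0888) and EB253887.1 (0.102) did not pass. With the authors' value table, 7.UF_CU.3.C3406 (0.0535) and CNSN01-C-006570-501 (0.0558) did not pass, and with plain background subtraction EB253887.1 (0.0501), CNSN01-C-006570-501 (0.0588) and 7.UF_CU.3.C3406 (0.0741) did not. With median centring EB349078.1 read -0.12 and EB253887.1 -0.19 (0.312 and 0.242). With replicates 6 and 7 left out, where fewer arrays were tested, CNSN01-F-092701-501_MINUS (0.0671), EB253887.1 (0.0854), 7.UF_CU.3.C3406 (0.103) and 7.UF_CU.3.C867_MINUS (0.128) did not pass. Such descriptions are old similarity hits to other organisms and do not establish what the Aplysia transcript encodes. An identifier ending in MINUS is taken here to mark the opposite orientation. Which strand such targets read was not established, among them the Hsp70-like and glutamic acid-rich targets and the binding protein of the next paragraph.

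Most of the 22 gene lists met few targets by description, and 13 had at least 1 tested member. Of the 20104 tested targets, 19754 had no similarity description, so list members among them could be met only through a name in the identifier. A list with few or no calls therefore does not show that its genes stayed unchanged. In the list of inducible transcription factors, the single tested member, similar to a snail cAMP-responsive element binding protein (CNSN01-F-087667-501_MINUS), had a log2 ratio of 0.13 ± 0.15 (SD, n = 8, limma adjusted p = 0.136) and was above 0 on 7 of 8 arrays. Adjusted over the list alone, 1 of 1 passed, against 0 over all targets tested. In a list of 1 member that adjustment changes nothing, and 4880 of all 20104 tested targets passed the threshold unadjusted. Passes over the list alone in this list, and in the lists of 1 or 2 members below, are therefore no evidence that the list changed. In the list of the sensitization literature, ACN4PKA fell and the binding protein did not pass, while adjusted over the list alone 2 of 2 passed. Kinases and phosphatases were met by ACN4PKA and by a kinase anchor protein (CNSN01-F-093207-501) at -0.11 ± 0.28 (SD, n = 8), of which ACN4PKA fell, and 1 of 2 passed adjusted over the list alone. Chaperones were met by the Hsp70-like target, which fell, and 1 of 1 passed adjusted over the list alone. Oxidative phosphorylation, with 10 tested members, and the cytoskeleton, with 3, were large enough for a list test, and 0 of their members rose or fell over all targets tested. Adjusted over the list alone, 1 of 10 passed in oxidative phosphorylation, an ATP synthase subunit 8-like target (PEG002-C-107274-501) with a log2 ratio of 0.16 ± 0.12 (SD, n = 8). That list's median log2 ratio was 0.02, and it was not past the threshold against other targets (limma camera adjusted p = 0.601, and 0.728 with an estimated correlation). A move of its members one way on balance did not pass either (limma fry adjusted p = 0.283), while change in either direction did (limma fry adjusted p = 0.0039). That last test is against no change, not against other targets: 2 of the 10 members had an unadjusted p under 0.05, as had 4880 of all 20104 tested. The cytoskeleton list had profilin-like, villin-like and midasin-like members at -0.07, -0.01 and 0.14, a median of -0.01 and a camera direction of up, so median and test differ in sign (limma camera adjusted p = 0.810, and 0.815 with an estimated correlation; limma fry adjusted p = 0.748, and 1 for either direction). The other lists' tested members did not pass: 2 of growth factor signalling (-0.09 and the same anchor protein), and 1 each for ribosomal proteins (-0.04), ubiquitin and proteasome (-0.11), neuropeptides (-0.02), ion channels (-0.06), chromatin (0.08) and connective tissue markers (-0.01). Adjusted over the list alone, 0 of these or of the cytoskeleton members passed. Reference genes and the muscle and hemocyte markers had no tested member, and translation factors, synaptic release, transmitter receptors, RNA binding, glia and neuron markers met no target. Of the 2 targets matched to the RefSeq table, dar1 had a log2 ratio of 0.05 ± 0.30 and LOC100861465 of 0.11 ± 0.34 (SD, n = 8, limma adjusted p = 0.760 and 0.538).

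Targets read by a probe with a GT repeat made up 143 of the 978 that rose and 1 of the 458 that fell, against 261 of the 20104 tested. At probe level, 243 of 389 repeat probes rose and 1 fell, and 62.5% of repeat probes rose against 4.24% of the others. With the repeat probes left out, 779 targets rose and 412 fell among 19998. A probe with 1 copy of TGTG holds no such repeat, yet 5.46% of these probes rose, against 2.72% of probes without TGTG. At 2 and 3 copies, where some probes may hold the repeat, 10.8% and 24.4% rose. The 779 are therefore not shown to be free of an effect of TGTG. In 50 targets with 1 repeat probe and 1 repeat-free probe that share no 12 bases, the repeat probes had a mean log2 ratio of 0.29 ± 0.03 (SE) and the repeat-free probes 0.04 ± 0.02 (SE), a difference larger than chance (permutation test over targets, one-sided p = 1e-05, the smallest 100000 draws can give). The 13 named targets include 1 with such a probe, CNSN01-F-107413-501.

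**Figure D2:**
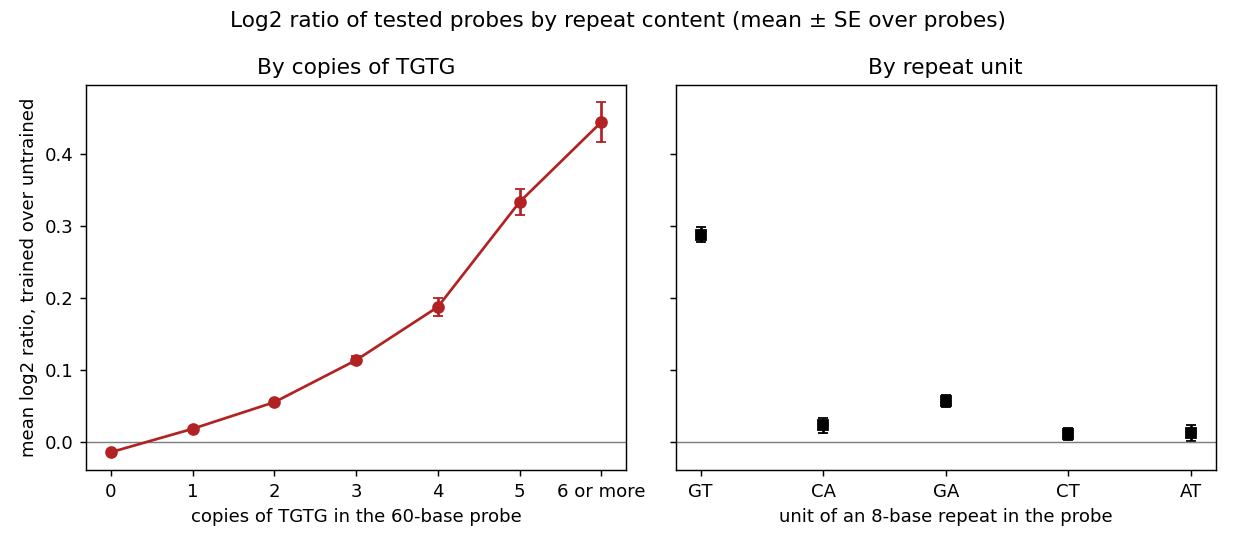
Mean log2 ratio of trained over untrained (± SE over probes) of the tested probes by copies of TGTG in the probe (left) and by the unit of a repeat of 8 bases (right). The mean goes from -0.01 without TGTG to 0.44 at 6 or more copies, and GT repeats read 0.29 while GA repeats read 0.06.

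Different probes of a target were set against each other as a further measure. Among 15742 targets with at least 2 probe sequences, 388 had all probes past the threshold with 1 sign, or 2.46%. Of the 2018 such targets with any probe past the threshold, 85.2% had probes of 1 sign, against 68.0% of all 15742. Probes that differ in sequence may still overlap and then share an effect of that sequence. These shares therefore do not separate such an effect from a change in RNA. Where 2 probes share no 12 bases (4821 targets), both passed with 1 sign in 84 targets, of which 52 rose and 32 fell, and both passed with opposite signs in 5.

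**Figure D3:**
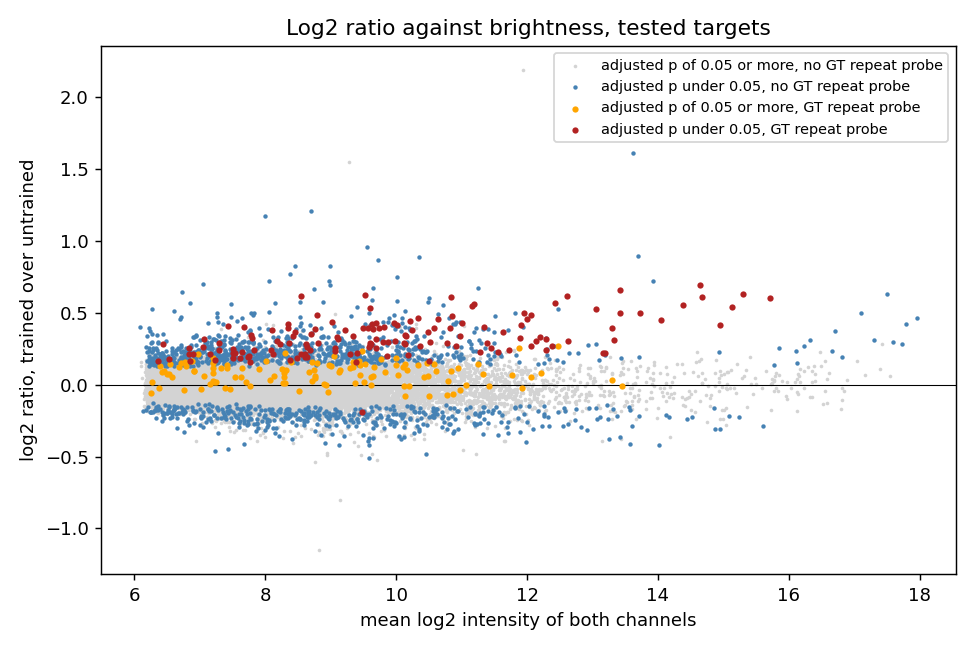
Log2 ratio of trained over untrained against the mean log2 intensity of both channels for the 20104 tested targets, coloured by whether the adjusted p is under 0.05 and whether a probe holds a GT repeat. Of the targets with a repeat probe, 143 passed above 0 and 1 below 0.

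All arrays carried the trained RNA in Cy5, so a dye effect common to the arrays enters every log2 ratio, and the calls depend on the removal of the intensity-dependent dye trend. With median centring in place of loess, 8981 targets rose and 1712 fell (84.0% rising against 68.1%), the median of all tested targets moved to 0.13, and ACN4PKA, 7.UF_CU.223.C1, 7.UF_CU.3.C3406 and CNSN01-C-006570-501 changed sign, the first 3 still below that median. CNSN01-C-006570-501 passed there as a rise, at 0.20 (limma adjusted p = 0.0232). With each array centred on the median of the tested probes instead, a setting chosen after the data were seen, 4270 rose and 5404 fell (44.1% rising). The trained and untrained channels of replicates 6 and 7 matched each other's array better than their own; crossing that pair gave 1260 targets that rose and 695 that fell, and leaving both out gave 733 and 331. The rows of the slide did not differ in any target (0 past the threshold, 820 at an unadjusted p under 0.05, limma, 4 arrays a row).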

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

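All tests on replicates 6 and 7 were chosen after the values were seen. Of 24 sets of 8 values examined for a single array far from the rest, 3 held one, and chance gives about 1 in 20. The helicase-like target CNSN01-F-074133-501 had a log2 ratio of -0.0124 on replicate 1, a gap of 0.738 of the range, and between 0.41 and 0.56 on the other arrays. The slope of the spike-in controls was lowest on replicate 7, at 0.818, and their correlation was lowest on replicate 8, at 0.986. Control spots for ERCC sequences were well above background in 6.22% of cases in the untrained channel and those named ETG in 8.25%, against 0.122% of the negative controls.

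A further pattern concerns replicates 6 and 7. On 6 of 8 arrays the trained channel, as deviations from the mean over arrays across 20102 targets, correlated best with its own untrained channel (r = 0.527 to 0.765, across genes, which are not independent replicates). The trained channel of replicate 6 correlated at 0.396 with the untrained channel of replicate 7 and at 0.080 with its own, and that of replicate 7 at 0.443 with the untrained channel of replicate 6 and at 0.197 with its own. Of 40320 ways to pair the channels, the one that crosses 6 and 7 alone had the highest total correlation. Arrays 6 and 7 lie side by side by the names of their tables, while the description of replicate 7 repeats the position of replicate 6 with a suffix, so the position of replicate 7 is in doubt; each table holds both channels of its array. For leaking of RNA between arrays 6 and 7, the first test was the correlation of the trained channels of replicates 6 and 7, which came out between the values set for and against it (r = 0.120, across genes) and left it open; the untrained channels of the same arrays, for which no bound had been written, correlated at 0.026. In the 18726 targets within 0.5 of a log2 ratio of 0 on both arrays, a selection that favours the pairing as labelled, channels of 1 dye correlated less well between arrays 6 and 7 than channels of different dyes (mean difference -0.149), but other pairs of arrays ranged from -0.207 to 0.119, so leaking stays open. A candidate explanation is that samples of 1 channel were exchanged: among these 18726 targets the pairing that crosses 6 and 7 alone still had the highest total correlation, by a small margin (4.31 against 4.19 as labelled). Other values follow from the correlations between the channels and are no separate evidence: 24 targets differed over 2-fold on both arrays with opposite signs and 5 with the same sign, and crossing gave 1955 targets past the threshold against 1436 as labelled. Whether trained or untrained samples would have been exchanged is open, and the mean log2 ratio over the 8 arrays does not depend on it.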

How the results depend on the processing

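The settings on probe sequence, on centring over tested probes and on replicates 6 and 7 were chosen after seeing the data. Of 36 alternatives for the count of 1436 targets past the threshold, 19 stayed within 1.5 times. Processed signals of the scanner software gave 847, median centring 10693, centring on the tested probes 9674 (4270 rose and 5404 fell), a test per probe 3328, and trend with robust variances 808 (764 rose and 44 fell). Ignoring which samples shared an array gave 321. Slide row 1 alone gave 212 and row 2 alone 25, with 4 arrays each. A fold of at least 1.2 gave 453, an adjusted p under 0.01 gave 380 and under 0.1 gave 2593, by construction. The dinucleotide correction gave 749, of which 633 were also called without it. Both of 2 non-overlapping probes passed in 84 of the 4821 targets that have them. Without 1 array the count lay between 713 and 1399, and it moved by over 1.5 times without replicate 1 (906), 3 (956), 4 (713) or 5 (874), where fewer arrays were tested. For the other settings that moved the count the cause was not tested.

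The share of targets with all probes past the threshold, 2.46%, was 0.889% with processed signals, 1.22% with plain subtraction and 38.5% with median centring, and the cause was not tested. The oxidative phosphorylation and cytoskeleton lists did not pass under any of their 15 alternatives each (limma camera adjusted p from 0.277 to 0.827 and from 0.646 to 0.972), nor did any target differ between slide rows under 11. With median centring the log2 ratios of gi_5587_emb_X62382.1_ACN4PKA_A.californica_ (0.0553), 7.UF_CU.223.C1 (0.115), 7.UF_CU.3.C3406 (0.0160) and CNSN01-C-006570-501 (0.204) reversed, the last also with centring on the tested probes (0.0617). Of these, CNSN01-C-006570-501 passed as a rise with median centring (limma adjusted p = 0.0232). The cause was not tested. U00994.1 passed in its direction under all 27 of its settings beside those that leave out 1 array. Of 349 such values for the 13 named targets, 271 kept direction and call, 73 kept direction alone and 5 reversed; with 1 array left out, 84 of 104 kept both and 20 kept direction alone. Leaving out saturated spots was void, as 0 were found, and the Aquantile step moved no log2 ratio. Signal over background limits 21 called targets, which were dim in 1 channel on all arrays.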

Other observations

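The tests on the repeat probes, on the sign patterns of the arrays and on covariation of the targets that rose were chosen after results had been seen; those on base composition, on partner probes and on ATTTA were chosen after the data had been seen but before their own results. The 2 most variable tested targets, whose probes share 12 bases, had log2 ratios from -1.85 to 5.38 and from -1.77 to 4.35 over the 8 arrays. They were above 0 on 6 arrays each and did not pass (means 2.19 and 1.55, limma adjusted p = 0.0806 and 0.108). The median SD over arrays of all tested targets was 0.143. Of 36 targets printed in both orientations, both forms were tested in 13, and 6 of these 13 pairs had 1 sign.

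Probes with a GT repeat read higher in the trained channel, with a mean log2 ratio of 0.29 over 389 probes, and the mean went with the copies of TGTG from -0.01 at 0 copies to 0.19 at 4 and 0.44 at 6 or more. A rise of the transcripts that carry the repeat is argued against by the repeat-free partner probes, whose mean was 0.0393 ± 0.0207 (SE, 50 targets), so an effect of the probe sequence is a candidate explanation. Over the 8 arrays the mean of the repeat probes followed the raw median of red over green (r = 0.747, exact permutation p = 0.0367, adjusted 0.0405 over 2 relations; rho = 0.762, exact permutation p = 0.0368; r = 0.749 without replicates 4 and 8), which suggests a part for the dye balance of the array; each slide row holds 4 arrays, too few to repeat this within rows. GA repeats, which would bind as many labelled cytosines, read 0.0564 ± 0.0083 (SE, 255 probes), so the number of cytosines stays open, as does a difference in an RNA pool that binds the repeats: repeat probes were brighter than their partners in 39 of 50 targets. The other relation computed was that of the first component of the arrays' deviations (28.7% of their variance) with the same raw median (r = 0.730, exact permutation p = 0.0405, adjusted 0.0405; rho = 0.905, exact permutation p = 0.0046; r = 0.762 without replicates 4 and 8).

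For the count of targets past the threshold, chance differences between the channels are argued against. Of 100 sign patterns of the 8 arrays, out of 128, 1 gave as many as the real 1436, the real one itself, and the highest of the others gave 6. A dye effect common to all arrays would also make the real pattern the highest, so the test cannot tell it from training. An effect of single probes as the whole cause is argued against by pairs of probes without TGTG. Among probes past the threshold, the non-overlapping partner had the same sign in 80.0% (116 of 145, exact 95% interval 72.6 to 86.2). After the dinucleotide content of the probes was regressed out, the share was 69.7% (62 of 89, interval 59.0 to 79.0). The lower limit of that second interval fell just short of the bound written beforehand, so the corrected share alone leaves the question open. Base composition may account for part: 44.1% of the targets called were still called after that correction (633 of 1436), among them U00994.1 at 1.52 and EB251115.1 at 1.25, which leaves it open as a cause for the rest. Lost calls alone do not point to composition, since a call can be lost with its size kept. 7.UF_CU.3.C3406 read -0.248 before and -0.245 after, while CNSN01-F-107413-501 went from 0.53 to 0.16. Over all targets the log2 ratios before and after correlated at 0.912. A dye effect of the whole labelled transcript cannot be told apart from training, since 0 arrays had the dyes swapped.

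A hypothesis was that an AU-rich element, common near the 3′ end of short-lived transcripts, marks the targets that rose. It was tested on targets with 2 non-overlapping probes, setting ATTTA in 1 probe against the composition-corrected log2 ratio of the other. The difference was -0.0032 ± 0.0042 (SE, 831 probes with ATTTA), and ATTTA ranked 6 among the 10 orders of its bases, so the data gave the hypothesis no backing.

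Another hypothesis was that some pools of animals responded more strongly, so that the targets that rose most vary together over the arrays. For the 20 largest rises without a GT repeat after U00994.1, the median correlation with U00994.1 over the 8 arrays was 0.0598, with a bootstrap interval over targets from -0.310 to 0.345. Random sets of 20 tested targets reached 0.229 at their 95th percentile, and the observed median lay at percentile 66.8 of them and at percentile 85.5 of sets drawn from other targets that rose. The result was negative in that the median did not exceed that percentile, which by the bound first written counts against the hypothesis. The bootstrap interval was added after the median was known, and it is too wide to exclude covariation.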
